A study of Mus musculus with 6 samples.

How the data were processed

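B cell progenitors from the bone marrow of C57BL/6 mice had been sorted by flow cytometry and profiled with the 10x Genomics 5' gene-expression and V(D)J assays. The 3 groups were wild-type mice of 12 weeks, wild-type mice of 100 weeks and IkB-deficient mice of 12 weeks. Each group gave 1 gene-expression and 1 V(D)J library, 6 libraries in all, each from a pool of 2 mice. The V(D)J library of a group was joined to its gene-expression library by cell barcode.

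The deposited matrices hold counts, that is raw UMIs per gene and called cell, made by the authors with Cell Ranger on the mm10 build. The release of Cell Ranger is not given, and the matrix headers name software version 3.0.1. Per the file headers the contig tables hold counts of UMIs and reads per contig, and all of their contigs are marked as high-confidence contigs of called cells. Per the file headers the clonotype tables hold counts of cells and a fraction, the share of each clonotype among all called cells of the library. These clonotypes were used only as an alternative.

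The young, aged and IkB-deficient matrices held 9647, 8046 and 9772 barcodes, 54698092, 50701225 and 78266890 UMIs, and medians of 3866, 4327 and 6534 UMIs per cell over 31053 genes. Cells with at least 500 UMIs, at least 300 genes and at most 10% mitochondrial UMIs were kept, which left 9509, 7850 and 9556. Doublets were scored with Scrublet in each library, and the top-scoring 7.79%, 6.57% and 7.98% (741, 516 and 763 cells, 0.8% per 1000 cells) were removed, where the automatic threshold of the tool called 272, 245 and 449. This retained 8768, 7334 and 8793 cells with medians of 3811, 4327 and 6414 UMIs and 1709, 1875 and 2428 genes. The V(D)J libraries held 31404, 22207 and 29168 contigs, of which 9843, 6129 and 1961 were productive, from 8965, 7169 and 9078 barcodes and 140492624, 141956901 and 149568227 reads.

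The 3 libraries were clustered together with no correction for library. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were taken without ribosomal, mitochondrial, immunoglobulin and T cell receptor genes, and Leiden clustering at resolution 1 ran on 15 neighbours in 30 principal components. Sex-linked genes were not left out of this step. Clusters were named "X-like" from 16 fixed marker sets. The thresholds for a name were set after the data were seen: at least 3 markers over 2-fold against all other clusters, a mean marker log2 of at least 0.5, a lead of 0.2 over the next class, and no other class with more of its markers among the cluster's top 10 genes. Clusters that missed them stayed unnamed and were left out of class comparisons. B-lineage cells were taken as all clusters not named plasmacytoid dendritic, NK or innate lymphoid or neutrophil lineage, which was also decided after the data were seen, so unnamed clusters are among them.

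For each class with at least 100 cells in both libraries, raw UMIs were summed per library and given as CPM over all genes other than immunoglobulin and T cell receptor genes, since these follow the V(D)J state. Log2 ratios had a pseudocount of 5 CPM, and folds are plain ratios of CPM with exact conditional binomial intervals. Genes with a mean CPM of at least 20 over the compared libraries counted as measured. For 22 gene lists the median log2 ratio of the measured members was given, where at least 3 were measured, with an interval from Poisson resampling of the counts and its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins. Shares have exact Clopper-Pearson intervals and sums of counts exact Poisson intervals. Where a count was 0, a floor of 3 counts was used.

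Genes were named by a fixed rule. Among genes of mean CPM of at least 20 with the same sign in all B-lineage classes, the 10 highest and 10 lowest by their smallest absolute log2 ratio were taken, with the 3 highest and 3 lowest of each class, the targeted genes and the 4 members of highest mean CPM of each list. Genes outside the rule are marked as such where they appear. Correlation and covariance of the aged and IkB-deficient log2 ratios were set beside 100 simulations in which only the young library was shared, and beside the values from young cells divided at random between the comparisons.

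A cell's heavy chain was its productive IGH contig of most UMIs. Segment usage, CDR3 length and clones were counted over all called cells of the V(D)J files, and a clone was a shared V, J and CDR3 nucleotide sequence. Clone shares were also taken over 1000 draws of 1117 cells per library. Cycling was read from G2 and M phase UMIs in cells thinned to 2000 UMIs.

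With 1 library per group, no p-value and no number of changed genes was computed. The steps were tested on simulated data: of 200 simulated changed genes, 50 at each of 0.25-fold, 0.5-fold, 2-fold and 4-fold, the sign was right and the interval excluded 1 in 100%, in aged small pre-B-like and in IkB-deficient pro-B-like cells. Intervals of unchanged genes excluded 1 in 8.73% and 7.38%. Of simulated lists, 20 of 20 raised ones, made of genes raised 2-fold or 4-fold, and 0 of 20 unchanged ones came above percentile 99. The simulated data held counting noise only, so they say nothing about differences between mice, libraries or clusters.

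The groups, comparisons, marker sets, gene lists, rule for naming genes and main alternatives were chosen before the data were examined. Alternatives covered the cell filter, doublets, clustering resolution, classes transferred from the young library, scaling, pseudocount, expression minimum, weighting of cells, contig filters, clone definitions and the thinning depth. The median log2 ratio of all measured genes stayed near 0 under each scaling. The choice of clusters 8 and 14 alone, for list medians and for the correlation, of cells with Y-linked UMIs only, and of leaving out cells of over 50 Jchain UMIs was added after seeing the data. The analysis used Python 3.11.15, scanpy 1.11.5 with its Scrublet routine, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, umap-learn 0.5.12, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.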

Results

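Bone-marrow B cell progenitors were compared between wild-type young mice (12 weeks), wild-type aged mice (100 weeks) and young mice that lack Nfkbie and Nfkbib and carry 1 working copy of Nfkbia (IkB-deficient, 12 weeks). The 3 genes encode inhibitors that hold NF-kB in the cytoplasm, so the comparisons address how age and loss of this inhibition go with the state of early B cells. Each group was 1 library per assay from a pool of 2 mice, so there were no replicates and no test between groups was made. The 95% intervals in the text cover counting error only. Genes are given by the symbol and Ensembl gene ID of the deposited feature lists, and positions by the mm10 assembly.

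All 3 targeted genes had fewer transcripts in the IkB-deficient library than in the young one, and Nfkbie was nearly absent. Over all retained cells Nfkbie (ENSMUSG00000023947, chromosome 17, 45555700 to 45563169) stood at 105 CPM (counts scaled to a class or library total of 1e+06) in young, 81.8 in aged and 2.64 in IkB-deficient cells, so that young cells were 39.7-fold higher than IkB-deficient cells (interval 34.2 to 46.4; 5068 and 179 UMIs). Nfkbib (ENSMUSG00000030595, chromosome 7, 28758251 to 28766644) stood at 56.3, 54.0 and 18.8 CPM, 2.99-fold higher in young than in IkB-deficient cells (2.80 to 3.20). Nfkbia (ENSMUSG00000021025, chromosome 12, 55489409 to 55492647) stood at 471, 357 and 242 CPM, 1.95-fold higher in young than in IkB-deficient cells (1.91 to 1.99). The 5' assay reads the start of a transcript, so a deletion further downstream need not remove the signal of Nfkbib. The 3 genes did not keep these ratios in each class, so the whole-library ratios also depend on the mix of classes, which differed between the libraries. In pro-B-like cells Nfkbie was 178 CPM in young and 2.28 in IkB-deficient cells (78.2-fold higher in young, 57.1 to 110), and Nfkbib was 35.5 and 22.9, while Nfkbia, itself an NF-kB target, was higher in IkB-deficient cells at 306 against 186 CPM (1.65-fold, 1.53 to 1.78). In cycling pro-B or large pre-B-like cells Nfkbia was lower in IkB-deficient cells, at 152 against 362 CPM, although these cells lay mostly in different clusters in the young and IkB-deficient libraries.

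The sex of the pools also differed between the groups. Y-linked UMIs without Xist were found in 63.1% of young cells, and Xist UMIs without Y-linked ones in 90.8% of IkB-deficient cells, while the aged library held 24.1% of cells with Xist and 43.1% with Y-linked UMIs. Genotype and sex therefore fall together in the IkB-deficient comparison, and the aged pool mixed both sexes.

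Small pre-B-like cells, which carry a rearranged heavy chain and rearrange the light chain, were the most abundant class in young mice, were fewer in aged mice and were scarce in IkB-deficient mice. They made up 55.3% (54.2 to 56.3) of retained young cells, 34.6% (33.5 to 35.7) of aged cells and 0.591% (0.442 to 0.775) of IkB-deficient cells. This share was 1.60-fold higher in young than in aged cells (1.54 to 1.66) and 93.5-fold higher in young than in IkB-deficient cells (71.2 to 123). The size of the IkB-deficient difference depended on how clusters were named. It was much smaller when IkB-deficient cells took the class of the young cells they resembled most, as given below. Pro-B-like cells, the earlier stage that rearranges the heavy chain, were 10.3%, 19.2% and 32.5%, with ratios to young of 1.87 (1.73 to 2.02) in aged and 3.17 (2.96 to 3.40) in IkB-deficient cells. The aged pool was uneven: against young cells with Y-linked UMIs, the pro-B-like ratio was 2.09 for aged cells with Y-linked UMIs and 1.26 for aged cells with Xist, and the small pre-B-like ratios were 0.598 and 0.550. Cycling pro-B or large pre-B-like cells were 14.8%, 14.3% and 14.6%, near-equal shares in the 3 libraries, but the class pooled different stages. A productive heavy chain was read in 94.3% and 97.2% of young cells in its clusters 10 and 11. It was read in 7.62% of young cells in cluster 14 and 4.76% of IkB-deficient cells in cluster 8. Cluster 8 held 1198 of 1283 IkB-deficient cycling cells, so the equal shares do not show that the large pre-B stage was kept. These shares are of cells sorted as B220-positive and negative for IgM, IgD and the markers CD3e, CD8a, CD11b, F4/80, Gr-1 and CD49b, so they do not give the composition of the marrow.

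Immature or mature B-like cells were 18.3% (17.5 to 19.2) of IkB-deficient cells, 0.0954% of aged cells (7 cells) and 0 of 8768 young cells, which allows a share of up to 0.0342%. Plasma cell-like cells were 1.53% of aged cells (112 cells), 0.114% of young cells (10 cells) and 0 of 8793 IkB-deficient cells, which allows up to 0.0341%. Plasmacytoid dendritic-like cells, which share B220 with B cells, were 4.38%, 4.43% and 13.1%, 2.98-fold higher in IkB-deficient than in young cells (2.67 to 3.34). The aged share was uneven too, at 10.1% of cells with Xist alone and 2.53% of cells with Y-linked UMIs alone, and the IkB-deficient library had Xist. Cells of cluster 5, scored as neutrophil lineage-like, were 2.06%, 7.68% and 7.64%. That cluster was mixed: at a finer resolution only 1 part, of 0.890%, 4.08% and 4.04% of cells, carried the granule genes Mpo (568 CPM) and Elane (328 CPM). The same part also carried the lymphoid gene Dntt (767 CPM), Flt3 (278 CPM) and the dendritic gene Siglech (347 CPM). The other parts carried Siglech at 599 and 598 CPM and Mpo at 8.54 and 0. These markers do not fix the cells of cluster 5 as neutrophils. NK or innate lymphoid-like cells were 0.456%, 1.39% and 1.51%. Summed markers of the neutrophil lineage reached 0.235, 0.612 and 1.33 CPM in pro-B-like cells of the 3 libraries, and those of conventional dendritic cells 9.41, 21.6 and 353 CPM, of which the MHC class II gene H2-Aa gave 345 CPM in IkB-deficient cells.

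Several classes were drawn from different clusters in different libraries. Pro-B-like cells lay in cluster 2 in the IkB-deficient library (2852 cells) and in cluster 3 in the wild-type ones (899 young and 1407 aged cells, against 9 IkB-deficient cells). Cycling cells lay in cluster 8 in the IkB-deficient library (1198 cells) and in clusters 10, 11 and 14 in the others, with cluster 14 taking 223 of 1302 young and 348 of 1049 aged cycling cells. Plasmacytoid dendritic-like cells lay in cluster 9 (1139 IkB-deficient cells) and cluster 12 (378 young and 311 aged cells), and the immature or mature B-like cells in clusters 4 and 20. A cluster made almost wholly of 1 library can reflect the library as well as a cell type. When IkB-deficient and aged cells instead took the class of the young cells they resembled most, the small pre-B-like share ratio of IkB-deficient to young cells was 0.351 in place of 0.0107 and the pro-B-like ratio was 2.65. Under a stricter cell filter the IkB-deficient pro-B cluster lost its name and the pro-B-like ratio was 0.00798, below 1. Clusters without a name held 12.6% of young, 16.8% of aged and 11.7% of IkB-deficient cells: cluster 7 held 1.80%, 4.73% and 9.78%, cluster 13 held 3.98%, 4.2% and 0.444%, cluster 15 held 3.55%, 2.29% and 0.171%, cluster 16 held 1.82%, 2.77% and 1.07%, and cluster 17 held 1.45%, 2.77% and 0.25%.

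**Figure D1:**
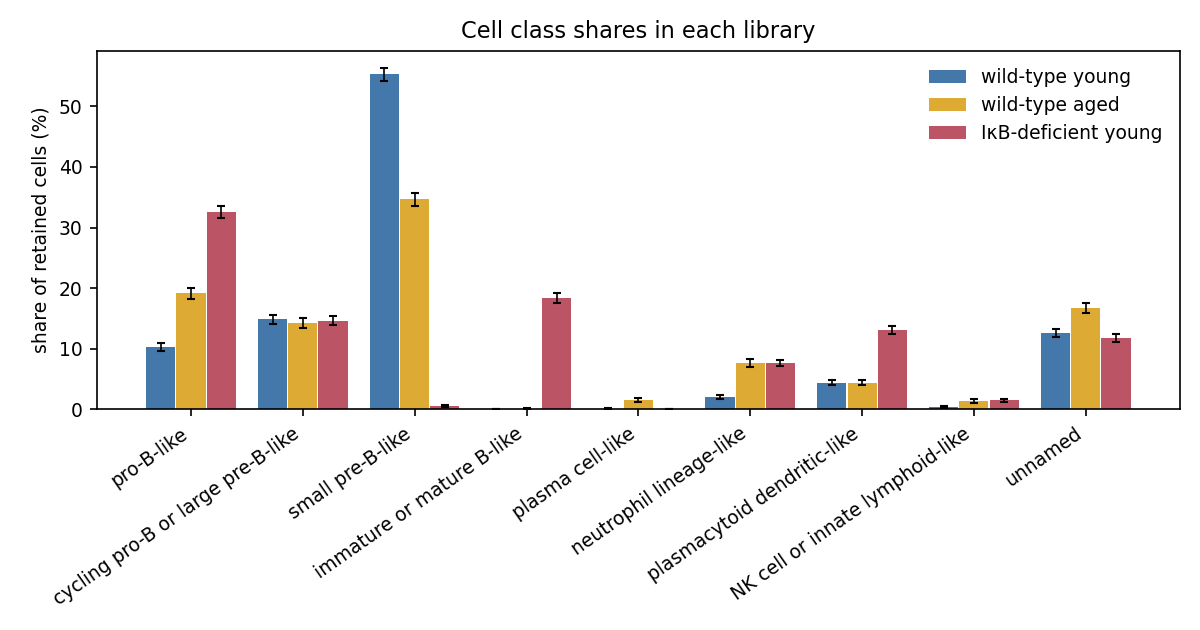
Share of retained cells in each class (percent, bars with 95% exact binomial intervals) for the wild-type young, wild-type aged and IkB-deficient young libraries. Small pre-B-like cells go from 55.3% in young to 34.6% in aged and 0.591% in IkB-deficient cells, and pro-B-like cells from 10.3% to 19.2% and 32.5%. Both IkB-deficient shares depend on how cells were given a class.

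IkB-deficient pro-B-like cells carried far more transcript of NF-kB target genes and of MHC class II genes than young pro-B-like cells. The MHC class II invariant chain, Cd74, was 2305 against 24.5 CPM (94.2-fold, 77.7 to 115). The cytokine subunit Ebi3 was 542 against 5.18 (105-fold, 69.2 to 167), and lymphotoxin beta, Ltb, was 1455 against 286 (5.09-fold, 4.80 to 5.39). The transcription factor Ebf1, needed to specify the B lineage, was 1612 against 4431 CPM, and Lef1 was 309 against 882.

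NF-kB target genes had a median log2 ratio of 1.39 in pro-B-like cells (1.28 to 1.53), at percentile 100 of random lists matched on expression, with 15 of 18 measured members above 0 and 12 over 2-fold. Among them Irf1 was 126 CPM in young and 305 in IkB-deficient cells, and Tapbp, a peptide-loading gene, 168 and 270. Birc3, an inhibitor of cell death, was 68.2 and 395, and the receptor Cd40 was 9.65 and 247; these 2 were chosen after their values were seen. The median stayed above 0 at other expression minimums, at 2.46 with a mean CPM of at least 100 and 0.79 with none. The NF-kB subunits as a list stood at a median of -0.11 with 2 of 5 members above 0, because they went both ways: Nfkb2, the precursor of p52, was 40.2 in young and 244 in IkB-deficient cells (6.07-fold, 5.21 to 7.11), and Relb 40.2 and 110, while Nfkb1 was 67.0 and 49.0 and Rela 53.6 and 46.7. In cycling cells Nfkb2 was 14 and 73.2. The inhibitor genes had a median of 0.41 in pro-B-like cells (3 of 5 above 0) and -1.52 in cycling cells (0 of 3).

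MHC class II genes had a median of 2.89 in pro-B-like cells (2.72 to 3.09; 7 of 8 above 0, percentile 100). H2-Aa was 6.82 CPM in young and 345 in IkB-deficient cells (50.6-fold, 35.2 to 75.7), H2-DMb2 was 4.47 and 130, and H2-Ab1 was 70.6 and 184, while H2-Ob, an inhibitor of peptide loading, was 300 and 228. The class II median depended on the low-expressed members, at 1.64 with a mean CPM of at least 100 and 3.32 with a pseudocount of 1. MHC class I genes had a median of 0.68 (13 of 14 above 0), with H2-K1 at 2348 and 3816, B2m at 2246 and 3585, and the immunoproteasome gene Psmb8 at 531 and 852.

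Interleukin-7 receptor signalling genes, which carry the survival and growth signal of these stages, had a median of 0.50 (0.43 to 0.61; 11 of 14 above 0). The common gamma chain Il2rg was 190 CPM in young and 499 in IkB-deficient pro-B-like cells, Pim1 was 203 and 318, and Il7r was near-equal at 295 and 325. Heat shock genes had a median of 0.47 with 7 of 7 above 0 (Hspa8 at 1446 and 2329). S phase genes stood at 0.25 (10 of 13 above 0), immediate early genes at 0.10 (8 of 14), glycolysis genes at 0.15 (7 of 12) and p53 targets at -0.10 (3 of 7). Apoptosis regulators were at 0.16 with 6 of 10 above 0, and among them the death agonist Bid was 53.2 and 285 CPM (5.36-fold higher in IkB-deficient cells).

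Interferon response genes were lower in IkB-deficient pro-B-like cells at a median of -0.55 (-0.65 to -0.37), with 11 of 15 below 0, and the direction turned to 0.24 with a mean CPM of at least 100. The abundant members went apart: Ifi27l2a was 270 CPM in young and 100 in IkB-deficient cells, while Gbp2 was 67.7 and 353. Oxidative phosphorylation genes stood at -0.37 (12 of 19 below 0). V(D)J recombination genes stood at -0.43 (5 of 9 below 0; 0.030 with no expression minimum), with Dntt, the enzyme that adds N nucleotides, at 2604 and 1543 CPM and the end-joining gene Xrcc6 at 1037 and 387. Rag1 was 281 and 155 and Rag2 was 291 and 215, both named after their values were seen. The surrogate light chain list stood at -0.18 (8 of 12 below 0), with Igll1 at 6460 and 6582 and Vpreb1 at 5423 and 4935. B-lineage transcription factors stood at -0.07 (10 of 18 below 0; 0.079 with median-of-ratios scaling), so that the low Ebf1 and Lef1 were set against near-equal Tcf3 (1240 and 1183) and Sox4 (491 and 466).

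Among genes that differed most in both pro-B-like and cycling cells were the serine protease inhibitors Serpina3g (13.6 and 320 CPM in pro-B-like cells; 23.5-fold, 18.1 to 31.0) and Serpina3f (32.2 and 338), the secreted Wnt ligand Wnt10b (0.941 and 193; 205-fold, 79.9 to 752), the phospholipase Gdpd3 (1.41 and 235), the trafficking gene Ehd3 (10.8 and 149), the surface proteins Ly6a (25.6 and 211) and Thy1 (6.35 and 61.5), and Gimap7 (31.5 and 201). Lower in both classes were Hist3h2ba (57.9 and 4.83), Rsph1 (62.3 and 8.72), the deacetylase Hdac5 (102 and 18.4), the adaptor Dok3 (228 and 57.3), the phosphatase Acp5 (53.6 and 11.7), Gm11808 (302 and 92.6) and Uchl1 (108 and 31.5). Xist, the X-inactivation RNA, was 0 and 530 CPM and the Y-linked Eif2s3y was 155 and 0, which follows the sex of the pools. The immunoglobulin constant gene Igkc was 72.9 and 1137 CPM in pro-B-like cells (15.6-fold, 13.9 to 17.5), Iglc3 was 10.6 and 319, Ighg2b was 11.1 and 73.4, and Ighm was near-equal at 1309 and 1215.

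Cycling IkB-deficient cells were also higher in NF-kB target and MHC genes: NF-kB target genes had a median of 0.69 (0.60 to 0.77; 10 of 14 above 0), MHC class II genes 1.10 (6 of 7) and MHC class I genes 0.67 (13 of 14). Ltb was 7.60 CPM in young and 475 in IkB-deficient cycling cells (62.6-fold, 51.8 to 76.4), and Cd74 was 279 and 1559. The young cycling cells lay mostly in clusters 10 and 11, where most cells carried a productive heavy chain. The IkB-deficient ones lay mostly in cluster 8, where few did. Single-gene values of cycling cells, here and above, can therefore reflect stage as well as library. All 11 glycolysis genes and all 8 heat shock genes were above 0, at medians of 0.62 and 0.56. All 20 G2 and M phase genes were below 0 at a median of -0.39, and the direction turned to 0.016 with transferred classes. Interferon response genes stood at 0.56 (5 of 6 above 0), oxidative phosphorylation genes at -0.39 and B-lineage transcription factors at -0.25, the last turning to 0.078 with transferred classes. Igll1 was 834 and 2725 CPM, Vpreb1 was 538 and 1723 and Dntt was 339 and 866, but the surrogate light chain list as a whole stood at 0.03 (6 of 12 above 0) and at -0.022 with clusters 8 and 14 alone. With clusters 8 and 14 alone, a choice made after seeing the data, the NF-kB target median was 0.82, the MHC class II median 2.67 and the interferon median -0.026. Jchain, 213 CPM in young and 0.228 in IkB-deficient cycling cells, came from few cells: 4 young cells held 99% of its young UMIs.

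Plasmacytoid dendritic-like IkB-deficient cells had higher MHC class II transcripts (median 2.02, 1.83 to 2.12; 10 of 10 above 0) and lower interferon response transcripts (median -2.02, -2.23 to -1.70; 1 of 9 above 0) than young ones, and NF-kB target genes stood at 0.55 (11 of 17 above 0). Cd74 was 3735 and 14791 CPM, H2-Aa was 928 and 4326, and Irf7, the regulator of interferon production in these cells, was 359 and 136; Irf7 was named after its values were seen. In unnamed cluster 7 the IkB-deficient to young medians were 0.68 for NF-kB target genes, 2.59 for MHC class II and -0.42 for the interferon response.

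**Figure D2:**
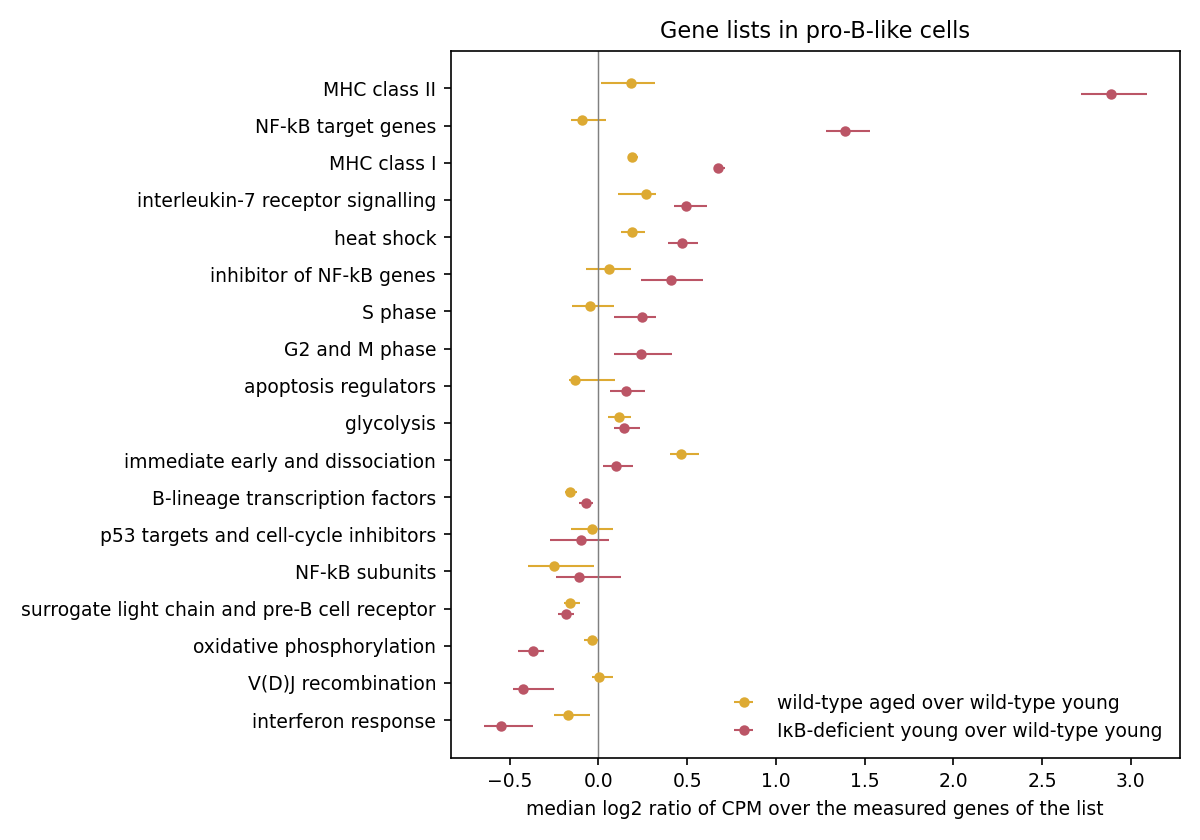
Median log2 ratio of CPM over the measured genes of each list in pro-B-like cells (points with 95% counting intervals), for aged over young and for IkB-deficient over young. The IkB-deficient points reach 2.89 for MHC class II and 1.39 for NF-kB target genes, where the aged points stand at 0.18 and -0.09.

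Aged small pre-B-like cells differed from young ones most in immediate early genes, which cells switch on within minutes of stimulation or of tissue handling. All 15 measured members were above 0, with a median log2 ratio of 0.95 (0.89 to 1.01), 7 over 2-fold, at percentile 100 of random lists. Fos was 421 CPM in young and 1457 in aged cells (3.46-fold, 3.35 to 3.57), and Egr1 was 8.78 and 42.3 (4.81-fold). Rela, the main activating NF-kB subunit, was 56.6 and 15.4 CPM, 3.66-fold higher in young cells. NF-kB target genes as a list did not differ, at a median of -0.03 with 7 of 17 above 0.

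The immediate early list was also higher in aged pro-B-like cells (0.47, 0.40 to 0.56; 13 of 14 above 0), cycling cells (0.27; 11 of 13) and plasmacytoid dendritic-like cells (0.38; 11 of 14), so it was not limited to 1 class. In small pre-B-like cells Jun was 1258 CPM in young and 2311 in aged cells, Ier2 was 111 and 301, the mRNA-decay factor Zfp36 was 1597 and 2468, Rhob was 112 and 315, the stress-response phosphatase subunit Ppp1r15a was 87.9 and 223, and Btg2 was 1017 and 1153. Fos was 310 and 774 in pro-B-like cells and 230 and 369 in cycling cells. Its list was made a main result only after its values were seen. The time and temperature of tissue handling are not given in the labels, and the same genes respond to both.

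Rela was lower in all 3 aged B-lineage classes, with 53.6 CPM in young and 15 in aged pro-B-like cells and 31.7 and 10.0 in cycling cells. The other subunits went less far, and the list median was -0.25 in pro-B-like cells (1 of 5 above 0), -0.13 in cycling cells (0 of 4) and -0.03 in small pre-B-like cells. NF-kB target genes stood at -0.09 in pro-B-like cells (5 of 14 above 0) and -0.03 in cycling cells (2 of 9). The inhibitor genes stood at 0.06 in pro-B-like, -0.05 in cycling and -0.0038 in small pre-B-like cells, and Nfkbia in small pre-B-like cells was 887 CPM in young and 1063 in aged cells. So the aged library did not carry the higher NF-kB target transcripts of the IkB-deficient one.

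MHC class I genes were slightly higher in aged cells, with medians of 0.19 in pro-B-like cells (11 of 14 above 0), 0.22 in cycling cells (12 of 13) and 0.08 in small pre-B-like cells (10 of 13). Among cells with Y-linked UMIs the small pre-B-like median was 0.018 (-0.015 to 0.125) and the pro-B-like one 0.17 (0.12 to 0.20), so within these cells the small pre-B-like interval held 0. In pro-B-like cells H2-K1 was 2348 CPM in young and 2709 in aged cells and B2m was 2246 and 2700. Interleukin-7 receptor signalling genes stood at 0.27 in pro-B-like cells (11 of 13 above 0), 0.07 in cycling cells and 0.09 in small pre-B-like cells. Among them the feedback inhibitors Socs2 (44.2 and 102 CPM) and Cish (18.6 and 37.2) were higher in aged pro-B-like cells, both named after their values were seen. Heat shock genes stood at 0.19, 0.21 and 0.13 in pro-B-like, cycling and small pre-B-like cells. Glycolysis genes stood at 0.24 in cycling cells (9 of 10 above 0) and 0.11 in pro-B-like cells.

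Aged pro-B-like cells were lower in surrogate light chain and pre-B cell receptor genes (median -0.16, 1 of 12 above 0) and in B-lineage transcription factors (-0.16, 3 of 17 above 0), with Spib at 289 CPM in young and 159 in aged cells. Interferon response genes stood at -0.17 in pro-B-like cells (5 of 17 above 0; 0.055 with a mean CPM of at least 100; -0.26, -0.46 to -0.15, among cells with Y-linked UMIs), -0.18 in small pre-B-like cells (0 of 6) and 0.09 in cycling cells. MHC class II genes stood at 0.18 in pro-B-like, -0.39 in cycling (0 of 6 above 0) and -0.13 in small pre-B-like cells, while in plasmacytoid dendritic-like cells they were at 0.79 (7 of 8 above 0), with Cd74 at 3735 and 7012 CPM. V(D)J recombination genes stood at 0.17 in small pre-B-like cells (7 of 8 above 0) and 0.00 in pro-B-like cells. S phase genes stood at -0.04, -0.07 and -0.04, G2 and M phase genes in cycling cells at -0.13 (18 of 20 below 0), oxidative phosphorylation genes at -0.03, 0.00 and -0.09, apoptosis regulators at -0.13, 0.10 and 0.08, and p53 targets at -0.04, -0.19 and 0.06 in pro-B-like, cycling and small pre-B-like cells.

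Among genes higher in all 3 aged classes were the mitochondrial mt-Atp8 (623 and 1258 CPM in small pre-B-like cells), Nme2 (45.1 and 73.0), Gng10 (19.5 and 32.9) and Oaf (19.4 and 46.3). Among genes lower in all 3 were the copper chaperone Cox17 (114 and 62.7), the ribosomal gene Rpl36al (190 and 98.2), the spliceosome gene Snrpg (211 and 128), Gm11808 (267 and 169) and the linker histone Hist1h1d (82.5 and 50.2). In pro-B-like cells the calcium-binding alarmin S100a6 was 33.6 and 179 (5.33-fold, 4.48 to 6.39) and Muc13 was 20.7 and 65.9, while Cass4 was 46.1 and 10.4 and Robo3 was 37.9 and 9.94. In small pre-B-like cells Col5a3 was 46.7 and 15.3, the linker histone H1f0 was 77.4 and 33.5, and Igll1 was 43.1 and 117. In cycling cells Gimap4 was 10.5 and 38.8, Hist1h2an was 34.1 and 8.33, Hist1h2af was 65.7 and 22.7, and S100a6 was 6.19 and 45.4. Xist was 0 CPM in young and 136 in aged pro-B-like cells, which follows the mixed sex of the aged pool.

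Across genes, the aged and IkB-deficient log2 ratios went together in the 2 B-lineage classes with at least 100 cells in each library. Small pre-B-like cells (4847 young, 2540 aged and 52 IkB-deficient) were left out because the IkB-deficient ones were below this minimum. Across 5578 genes in cycling cells the correlation was 0.711 and the covariance 0.0926, where simulated libraries with no shared effect gave 0.492 and 0.00226 from the shared young library. Across 6001 genes in pro-B-like cells the correlation was 0.367 and the covariance 0.0495, against simulated values of 0.700 and 0.00790. With the young cells divided at random, so that each comparison had its own, the correlations were 0.686 and 0.282, and the covariances 0.0906 and 0.0415, against simulated correlations of 0.00172 and -0.00290. The covariance beyond the simulated one estimates what is shared and was 0.0904 and 0.0416, whereas a difference of correlations does not. The cycling cells of the aged and IkB-deficient libraries both lay more in clusters 8 and 14 than the young ones. With these 2 clusters alone, a choice made after seeing the data, the covariance beyond the simulated one was 0.0485 (correlation 0.581, simulated 0.714) across 5648 genes. Genes are not independent replicates, and both sets of young cells still come from 1 young library, so what sets that library apart from both others is part of the shared value. Sex is among these traits, since the young library alone held almost no Xist.

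Productive heavy chains were found in most young cells, in fewer aged cells and in few IkB-deficient cells. A productive IGH chain was read in 75.2% of retained young cells (74.3 to 76.1), 53.5% of aged cells (52.3 to 54.6) and 11.2% of IkB-deficient cells (10.6 to 11.9). Cycling cells carried one in 80.6%, 63.8% and 10.1%, and pro-B-like cells in 9.12%, 9.67% and 4.16%. In clusters 10, 11, 13 and 16, which all 3 libraries shared, the shares were 95.3%, 89.0% and 90.7% (194 of 214 IkB-deficient cells), and in small pre-B-like cells 95.3%, 91.7% and 71.2% (37 of 52). NK or innate lymphoid-like cells should lack such chains. A productive IGH chain was read in 2.50% of young ones (1 of 40), 0 of 102 aged ones (allowing up to 2.94%) and 0 of 133 IkB-deficient ones (up to 2.26%). Their median depths were 5202, 4329 and 5546 UMIs against 3811, 4327 and 6414 over all retained cells. Other classes not counted as B-lineage carried more in the wild-type libraries. Plasmacytoid dendritic-like cluster 12 had 4.76% of young (18 of 378) and 1.29% of aged cells, against 0.615% in IkB-deficient cluster 9. The mixed cluster 5 had 7.73%, 4.26% and 0.595% of young, aged and IkB-deficient cells. Shares were not corrected for such reads, so the pro-B-like difference between young and IkB-deficient cells can reflect background.

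**Figure D3:**
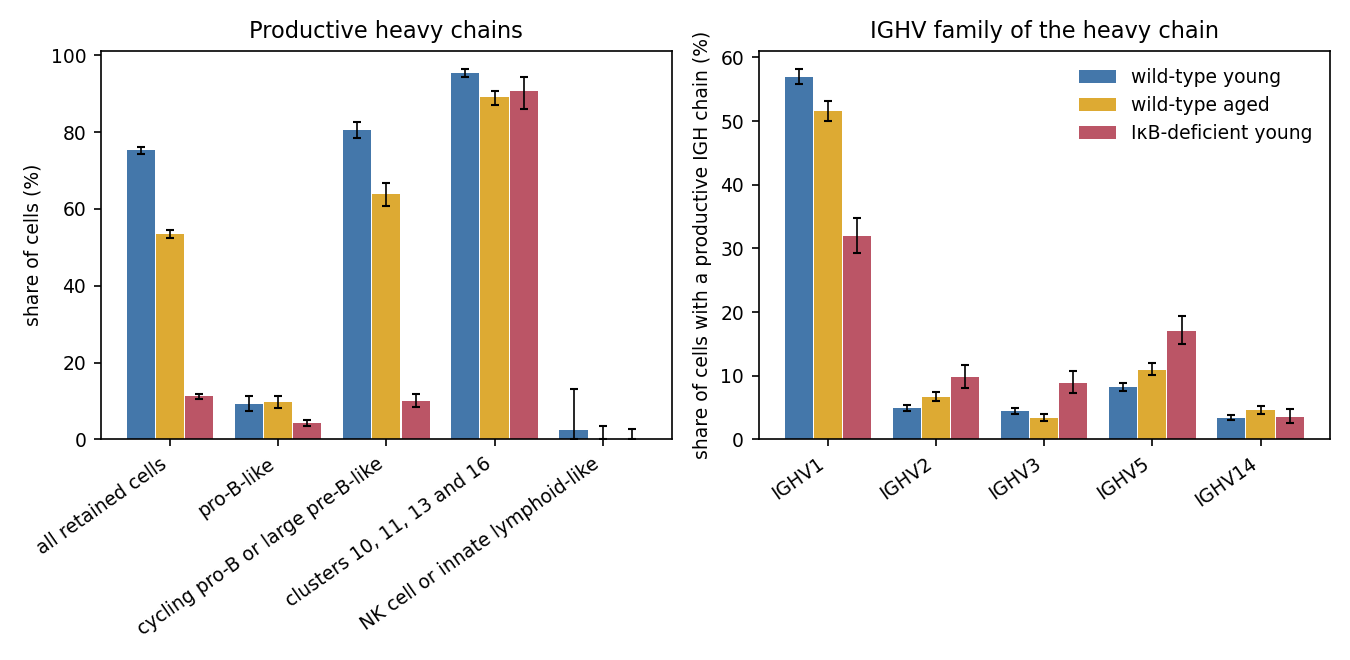
Share of cells with a productive IGH chain by class (left, percent), and share of each IGHV family among cells with such a chain (right, percent), with 95% exact binomial intervals, for the 3 libraries. Over all retained cells the share is 75.2% in young, 53.5% in aged and 11.2% in IkB-deficient cells, and IGHV1 takes 57.0%, 51.6% and 32.0% of the chains.

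Light chains without a heavy chain were more frequent in the IkB-deficient library. A productive light chain was read in 19.2% of young, 16.5% of aged and 7.95% of IkB-deficient cells, and a light chain without a productive heavy chain in 1.28%, 2.05% and 6.76%. In pro-B-like cells the last share was 1.11% (10 cells), 1.71% (24 cells) and 8.32% (238 cells; 7.33 to 9.39), with median contig depths of 1.5, 1 and 21 UMIs. Igkc UMIs were in 22%, 9.45% and 89.4% of pro-B-like cells, against 10.0%, 0% and 3.01% of NK or innate lymphoid-like cells, at median depths of 4460, 4361 and 6043 UMIs in the main pro-B-like clusters. Igkc was not particular to pro-B-like cells: plasmacytoid dendritic-like cells carried it in 88 of 384 young, 43 of 325 aged and 827 of 1149 IkB-deficient cells, at 464, 97.4 and 1233 CPM, and neutrophil lineage-like cells at 48.3, 17.4 and 166 CPM. In the young plasmacytoid dendritic-like cells 1 cell with over 50 Jchain UMIs held 911 of 1162 Igkc UMIs, and without it, a choice made after seeing the data, they had 101 CPM. Productive light chains without a heavy chain were read in 0.521%, 1.23% and 0.435% of plasmacytoid dendritic-like cells. Among the immature or mature B-like IkB-deficient cells, 32.9% carried a productive IGH chain and 22% a productive light chain, low shares for cells of that stage, and the sort had removed cells with surface IgM or IgD.

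The heavy chains called used different gene segments in the 3 libraries, which drew them from different cells: 4619 of 7311 young chains came from small pre-B-like cells, and 531 of 1117 IkB-deficient chains from immature or mature B-like cells. The Igh haplotype of the IkB-deficient mice is not given, and V gene calls depend on it. IGHV1, the large family far from the D segments, was used by 57.0% of 7311 young cells, 51.6% of 4366 aged cells and 32.0% of 1117 IkB-deficient cells. The near families IGHV5 and IGHV2 together were used by 13.2%, 17.7% and 26.9%. IGHJ4, the J segment farthest from V, was used by 32.1%, 22.1% and 15.1%, and IGHJ2 by 25.1%, 31.9% and 35.7%. Among single V genes, IGHV1-26 took 5.44%, 4.56% and 3.31%, IGHV5-9-1 took 0.629% of young and 4.83% of IkB-deficient cells, and IGHV3-1 took 0.287% and 4.12%. The heavy-chain CDR3, the part made at the junctions, had a mean length of 14.4, 14.3 and 13.7 amino acids (SD over cells 2.90, 2.87 and 2.72). Lambda made up 13.5%, 11.7% and 9.87% of light chains. The constant gene was other than IGHM or IGHD in 0.191%, 1.63% and 0.179% of cells.

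Shared heavy chains were rare, and were most frequent at equal cell numbers in the IkB-deficient library. Clones of at least 2 cells held 4.28% of young cells with a productive IGH chain (3.83 to 4.77), 7.72% of aged cells (6.94 to 8.55) and 9.31% of IkB-deficient cells (7.67 to 11.2). At 1117 cells drawn from each library the shares were 0.799%, 2.88% and 9.31%, with 1112, 1099 and 1060 distinct rearrangements. The draw kept every IkB-deficient cell but only part of the 7311 young and 4366 aged ones, which separates cells of a clone in those libraries. Equal cell numbers are thus not equal fractions of the cells read, and without the draw the aged and IkB-deficient intervals overlapped. The clone of most cells held 8, 18 and 4 cells, and 8, 11 and 4 with IGH contigs of at least 3 UMIs. By deposited clonotypes it held 7, 17 and 19, so the order of the libraries depended on the definition. Deposited clonotypes are not a like measure of shared heavy chains. They covered 1786 IkB-deficient cells, where 1117 had a productive IGH chain, and so also grouped cells without one. The aged clone of 18 cells joined IGHV1-64 to IGHJ1 with the CDR3 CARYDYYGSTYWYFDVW, carried IGKV6-15 in 18 of 18 cells and lay in plasma cell-like cells in 14 of 18, and clones held 23.8% of the plasma cell-like aged cells with a heavy chain.

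Cycling cells of all B-lineage stages together made up near-equal shares of B-lineage cells in the 3 libraries. With every cell thinned to 2000 UMIs, at least 2 UMIs of G2 and M phase genes were found in 32.5% of young (31.4 to 33.5), 32.9% of aged (31.7 to 34.1) and 32.5% of IkB-deficient cells (31.4 to 33.7), and without thinning in 40.9%, 37.5% and 44.7% at median depths of 3647, 3835 and 6253 UMIs. Thinning left out 485, 640 and 146 cells. The thinned share in NK or innate lymphoid-like cells was 2.56% (1 of 39), 0 of 99 (allowing up to 3.03%) and 12.9% (17 of 132), so these cells give no clean background in the IkB-deficient library, and in plasmacytoid dendritic-like cells it was 2.65%, 0.943% and 1.42%.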

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

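The tests of the sex of the pools and of doublets were set before their results were seen, while the tests of free RNA, of the V(D)J yield and of the share of cell classes were chosen only afterwards.

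In the IkB-deficient library 7.96% of retained cells carried an IGHG2B contig with no V gene (7.40 to 8.55), against 0.616% of young and 0.954% of aged cells, a signal in contigs that the comparisons of productive chains do not use. Cycling IkB-deficient cells carried it in 15.5% and pro-B-like cells in 6.36%. Wild-type cells of like clusters carried it too: cluster 7 in 6.96% of young, 6.05% of aged and 21.5% of IkB-deficient cells, and cluster 14 in 8.52% of young and 3.16% of aged cells against 16.6% in cluster 8 of the IkB-deficient library, so part of the difference between whole libraries goes with their clusters. In the IkB-deficient library it was read in 0 of 133 NK or innate lymphoid-like cells, which allows up to 2.26%, and in 0.348% of plasmacytoid dendritic-like cells. A contig with a constant gene and no V gene is what transcription of the unrearranged IgG2b locus would leave, but no explanation of it was tested.

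Sex-linked transcripts, which no comparison was built on, split the aged library: 24.1% of its cells had Xist and no Y-linked UMIs, and 43.1% had Y-linked UMIs and no Xist, so the aged pool held mice of both sexes. The cells with Xist and with Y-linked UMIs also differed in class, with pro-B-like shares of 13.9% and 23.1% and plasmacytoid dendritic-like shares of 10.1% and 2.53%. As the pool held 2 mice, this split is also a split between individual mice, and sex and mouse cannot be separated in it.

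Nfkbia went opposite ways in the 2 B-lineage classes of the IkB-deficient comparison, with a log2 ratio of 0.70 in pro-B-like cells and -1.23 in cycling cells. It stood out because the direction differed between classes. The difference between the classes was not tested, since each class came from 1 library per group, and the cycling cells of the 2 libraries lay in different clusters.

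The higher NF-kB target and MHC class II transcripts of IkB-deficient pro-B-like cells were set against the sex of the pools and free RNA from other cells. Between aged pro-B-like cells with Xist and with Y-linked UMIs the NF-kB target median was 0.036, under 0.25 of the IkB-deficient median, which argues against sex as its source. The MHC class II median was -0.13, but the bound had been set for the NF-kB target list only. These cells come from 1 mouse of each sex at 100 weeks, so sex is not separated from mouse and 12 weeks is not covered. After free RNA at the highest level of 6 B-lineage and dendritic genes in NK or innate lymphoid-like cells (0.628% of the library profile) was taken off every member, the medians were 1.38 for NF-kB targets and 2.88 for MHC class II, nearly as before. Earlier forms of this test were set aside after their values were seen: the ratio of Cd74 in NK or innate lymphoid-like to pro-B-like cells, 0.302, lay between its bounds, and taking off the whole level of these cells left 0.08 for NF-kB targets, of which they express Slfn2, Tapbp and Irf1 at 269, 323 and 166 CPM, and 2.48 for MHC class II, although H2-Aa and Cd74 stood in them at 8.47% and 17.4% of the library level, above the 0.628% taken off. The loss of the inhibitors, which the design names, may explain the pattern and remains a hypothesis, since genotype was not varied apart from the library.

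The low share of productive heavy chains in the IkB-deficient library was set against a poor V(D)J library and against the mix of cell classes. In clusters 10, 11, 13 and 16 the IkB-deficient share was 0.951 of the young one, which argues against a poor library as the whole cause, though small pre-B-like cells had 71.2% (37 of 52; 56.9 to 82.9) against 95.3%, so a somewhat lower yield is not excluded. Young shares were applied within matched clusters (2 to 3, 8 to 14 and 9 to 12) to 7180 cells, without 1613 immature or mature B-like cells. The expected share was 11.4% and the observed one 6.38%, where young cells as a whole had 75.2%. So the mix of clusters went with most of the low share. The remaining 5.04 points (3.76 to 6.38) lay above 0 by counting error but straddled the bound of 5 points, so the test stayed undecided. Young dendritic cells of cluster 12 had 4.76% against 0.615% in cluster 9, so background in the young shares can be part of the remainder. Matching by class had given an expected 23.5% and a difference of 17.1 points, and was replaced after its value was seen because the cycling class mixes cells before and after heavy-chain rearrangement. A developmental stop before the pre-B stage by genotype could also leave this pattern and was not tested.

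The light chains without heavy chains in IkB-deficient pro-B-like cells were set against free RNA and doublets. Igkc in NK or innate lymphoid-like cells was 0.0041 of its level in pro-B-like cells, which argues against free RNA. Pro-B-like cells with a light chain alone had 0.972 of the median UMIs of those with none (5890 and 6062), where doublets would have more, and Igkc was 1122 and 1137 CPM in them. The top-scoring doublets had been removed first, so this comparison covers only doublets that the removal missed. Plasmacytoid dendritic-like IkB-deficient cells had as much Igkc (1233 CPM, young 464, or 101 without 1 young cell of many Jchain UMIs) with Cd79a at 18.4 CPM, but light chains without heavy chains in 0.435%, so the higher Igkc was not confined to B-lineage cells, while the rearranged chains were fewer in these cells. Light-chain transcription and rearrangement ahead of the heavy chain in the absence of the inhibitors may be one source, as a hypothesis found and examined on the same data that leaves the Igkc of dendritic cells unexplained.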

How the results depend on the processing

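The settings with Y-linked UMIs alone, with clusters 8 and 14 alone and without cells of over 50 Jchain UMIs were chosen after the results were seen, and so were the clusters counted as B-lineage. Of 861 list medians under alternatives (88 results), 710 lay within their counting interval, 126 lay outside it in the same direction and 25 reversed. Of 153 class shares (24 results), 68 lay within it and 85 outside. Of 157 other values (46 results), 89 lay within it, 67 outside and 1 reversed. Except where construction shows it, the cause was not tested.

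With a mean CPM of at least 100, which leaves fewer genes in each list, the IkB-deficient pro-B-like medians were 1.64 for MHC class II and 2.46 for NF-kB targets, and the aged small pre-B-like immediate early median was 0.63. The interferon median turned to 0.24 in IkB-deficient and 0.055 in aged pro-B-like cells, the immediate early median to -0.038 in IkB-deficient cycling cells, and the pro-B-like correlation was 0.446. With no expression minimum these were 1.64 (MHC class II), 0.79 (NF-kB targets) and 0.76 (immediate early), and in IkB-deficient pro-B-like cells G2 and M phase turned to -0.33 and V(D)J recombination to 0.030, and in cycling cells V(D)J recombination to 0.068 and p53 targets to 0.033. A pseudocount of 1 gave 3.32 for MHC class II. CPM without ribosomal and mitochondrial genes gave 1.97 for it and -0.0090 for the surrogate light chain list in IkB-deficient cycling cells. Median-of-ratios scaling gave 0.24 for MHC class I in aged pro-B-like cells, 0.079 for B-lineage transcription factors in IkB-deficient and 0.013 for oxidative phosphorylation in aged pro-B-like cells. The mean over cells gave 1.01 for the aged immediate early median, and -0.024 for G2 and M phase and -0.029 for apoptosis in IkB-deficient pro-B-like cells.

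With doublets kept, the IkB-deficient to young pro-B-like share ratio was 2.55, G2 and M phase turned to -0.22 and immediate early genes to -0.063 in pro-B-like cells, and S phase to -0.12 in cycling cells. Under the strict filter the small pre-B-like ratio was 0.00793, S phase in cycling cells -0.087 and the pro-B-like ratio 0.00798, because the cluster of most IkB-deficient pro-B-like cells lost its name, which left 7 IkB-deficient cells in the class and no list values for it. With transferred classes the ratios were 2.65 (pro-B-like) and 0.351 (small pre-B-like) for IkB-deficient and 0.661 (small pre-B-like) for aged cells. In cycling cells this setting turned B-lineage transcription factors to 0.078, G2 and M phase to 0.016, S phase to -0.27, V(D)J recombination to 0.11 and p53 targets to 0.12 in the IkB-deficient, and S phase to 0.0092 and apoptosis to -0.0032 in the aged comparison. Resolution 0.5 gave a pro-B-like ratio of 2.94, resolution 2 a small pre-B-like ratio of 0.00744, and no cell filter one of 0.0520, for IkB-deficient cells. Clusters 8 and 14 alone gave -0.026 for the interferon response and -0.022 for the surrogate light chain list, and a correlation of the comparisons of 0.581. Cells with Y-linked UMIs alone gave aged to young ratios of 2.09 (pro-B-like) and 0.598 (small pre-B-like), against 1.26 and 0.550 for aged cells with Xist, and an MHC class I median of 0.018 in small pre-B-like cells. Without cells of over 50 Jchain UMIs, Igkc in young plasmacytoid dendritic-like cells was 101 CPM.

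Nfkbie was 78.2-fold higher in young than in IkB-deficient pro-B-like cells and 18.3-fold in cycling cells. Dividing the young cells at random between the comparisons gave a pro-B-like correlation of 0.282, since no counting noise is then shared. In the order young, aged and IkB-deficient, productive IGH was read in 80.4%, 61.3% and 14.3% of B-lineage cells and in 81.6%, 60.9% and 12.3% of all V(D)J barcodes, and with full-length, high-confidence contigs of at least 3 UMIs in 73.6% of young and 51.3% of aged cells. Clones held 3.57%, 6.15% and 7.05% of cells with IGH contigs of at least 3 UMIs, and 3.80% of young and 6.55% of aged retained cells. They held 3.19%, 6.44% and 14.8% by deposited clonotypes, which also group cells without a heavy chain. G2 and M phase UMIs were found in 26.2%, 28.8% and 27.9% of cells with at least 3 UMIs asked for, in 40.9%, 37.5% and 44.7% without thinning and in 24.5%, 25.8% and 26.5% at 1000 UMIs, as fewer UMIs or a higher minimum must lower the share. No paired analysis was possible because each group is 1 library.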

Other observations

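Within the aged library, pro-B-like cells with Xist had higher interferon response transcripts than those with Y-linked UMIs, at a median log2 ratio of 0.67 (0.44 to 0.76). Over aged cells with Xist alone, IkB-deficient pro-B-like cells had medians of 1.61 for NF-kB target genes (1.33 to 1.79), 1.68 for MHC class II, 0.40 for MHC class I, 0.28 for interleukin-7 receptor signalling and -0.86 for the interferon response, so the directions of the young comparison held against aged cells of the same sex signal, 245 pro-B-like cells that come from 1 mouse, as the aged pool held 2 mice and both sexes. Small pre-B-like cells were 28.1% of aged cells with Xist and 30.5% of those with Y-linked UMIs, against 51.1% of young cells with Y-linked UMIs.

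The list of memory, age-associated and activated B cell genes had too few measured genes for a median in B-lineage classes, and in plasmacytoid dendritic-like cells its median over 4 genes was -0.08 in aged and -0.76 in IkB-deficient cells over young ones. Cluster 7, unnamed, carried Nfkbia at 94.8 CPM in young and 149 in IkB-deficient cells, and its aged interferon response median was -0.36 with 0 of 10 genes above 0. Heavy-chain contigs in plasmacytoid dendritic-like cells lay in clones in 42.1% of young (8 of 19), 0% of aged (0 of 5, allowing up to 60%) and 57.1% of IkB-deficient cells (4 of 7), all small numbers.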
